A study of Sus scrofa with 18 samples.

How the data were processed

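Backfat was taken at a commercial slaughterhouse from 18 Italian Large White pigs and frozen, total RNA was extracted with Trizol, and small RNA libraries were made with the TruSeq Small RNA kit and sequenced on an Illumina GAII as single-end reads of 100 bases with 2 samples per lane, per the labels' protocols. The labels call the molecules mRNA in the sample titles, but the kit, the series description and the read sequences are those of small RNA.

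The authors deposited a table of raw counts, whole numbers of reads for each sequence variant of each mature miRNA within an extended hairpin precursor, and a table of normalised counts. In the normalised table the deposited signal of each library equals the raw count divided by 1 size factor per library, from 0.464 to 1.93, as found by dividing the deposited tables. Bowtie 0.12.7, HTSeq (version not given in the sources used here) and DESeq2 1.4.5 with the genome build Sscrofa10.2 are named per the submitters' processing notes, which give no role or order. Adapter trimming, length filters and the number of mismatches allowed are not given in the sources used here. The deposited table gives each variant a category: an exact match to the mature sequence, a shorter or longer form, or a form with 1 or 2 mismatches. Such a table cannot tell a sequencing error, an RNA edit and an added base apart.

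Columns were tied to samples by the animal number and library code in the sample descriptions, and groups came from the backfat class and sex in the labels. The tables hold 2 further columns of values that match no sample, and these were not used. A read sequence that fits several precursors is listed under each: 3474 sequences were listed more than once, 3468 of them with identical counts in every listing, so library totals were taken over distinct sequences. Precursor positions come from the deposited table and include both ends, and whether they count from 0 or 1 is not stated. No genome of the build used by the authors was at hand, so no genomic coordinates are given, and neighbouring miRNA genes (within 10000 bases) were taken from an annotation of Sscrofa11.1 by name.

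Fits used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9. The main test was edgeR's quasi-likelihood F test on raw counts after filterByExpr (minimum count 10) and TMM scaling, with Benjamini-Hochberg adjustment and a threshold of 0.05. High was compared with low backfat with sex as an additive covariate, castrated males with females with backfat class as a covariate, and the contrasts within each sex and their difference in a fit of 4 cells of sex by class that shared 1 estimate of spread. Each was run on 7330 single entries of the table. An entry is 1 read sequence under 1 precursor and 1 mature miRNA. Numbers of sequence forms tested or called below are numbers of entries, unless each sequence was counted once. The comparison of high with low backfat was also run on 221 mature miRNAs after summing their variants. There each read sequence was counted once per mature miRNA, at its highest listed count. A sequence shared between miRNAs counts under each of them, so shares of single miRNAs can sum to more than 100%. Fold changes are log2 with SE, and log2 CPM used a prior count of 2. SE was derived from the F statistic, CPM is counts per 1000000 after TMM scaling, and p-values from these fits measure the spread between animals.

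Before the data were examined, 15 lists of miRNAs were fixed from general knowledge of their roles and cell types, and lists with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01, with camera's estimated correlation and fry beside it. The lists overlap. Shares of counts per category were compared with exact two-sided permutation tests of 9 against 9. The rule for named miRNAs, also fixed before, took all entries past the threshold if 30 or fewer, otherwise the 15 lowest p in each direction (the 10 lowest p if fewer than 10 passed), the 15 most abundant mature miRNAs, the 4 most abundant members of each list, and miR-21, miR-143, miR-103, miR-10b, miR-122 and miR-378, which gave 53 mature miRNAs. Other miRNAs that are named, and those named in the within-sex and interaction contrasts of summed miRNAs, were chosen after their values were seen.

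Alternatives fixed before were DESeq2 size factors in the edgeR fit, no low-count filter, a minimum mean of 10 CPM, DESeq2's Wald test, limma on log2 of the deposited normalised count plus 1, no sex term, age or the run of library codes as a covariate, each sex fitted alone, and leaving out each library in turn. Chosen after seeing the data were the rule of counting a repeated sequence once per miRNA (and its alternative of summing all listings), counting each distinct sequence once, exact and length variants only (in edgeR and DESeq2), a term for sets of libraries that share sequencing errors, leaving out high replicates 6 and 8, leaving out the 4 libraries coded AC485 to AC488, the contrasts of sex, interaction and each sex on summed miRNAs, and the test of the lists between the sexes. The runs of library codes (4 runs of 4, 4, 6 and 4 libraries) were read from the sample descriptions, and their meaning is not stated. Sets that share errors were found by clustering the libraries' rates of single-base substitutions at read positions 1 to 19, which gave 8 sets: 7 pairs and the 4 libraries coded AC485 to AC488 (correlation of at least 0.956 within and at most 0.873 between sets).

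The edgeR step was also tested on simulated counts with the real means, depths and spread, after first fits to the real data had been made. For high against low backfat, with 40 of 221 miRNAs changed in 20 simulated sets, 87% of 2-fold and 54.2% of 1.5-fold changes were found with 4.07% false calls. With 200 of 7330 entries changed in 5 sets, 52.2% of 4-fold and 13.8% of 2-fold changes were found with 3.51% false calls. A shift of 0.5 on the log2 scale in the fibrosis list was found in 20 of 20 sets, with 0 calls among the lists that share no member with it. The simulated miRNAs varied independently, while the estimated correlation of this list in the real data was 0.215. The simulation therefore does not show how often lists are called falsely in the real data.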

Results

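Small RNA libraries were examined from the backfat, the subcutaneous fat along the back, of 18 Italian Large White pigs, 9 with high and 9 with low backfat deposition. The high class held 4 females and 5 castrated males, and the low class 5 females and 4 castrated males. All animals weighed 150 to 160 kg. Age was 241 ± 4.47 days in the high class and 243 ± 6.04 days in the low class (SD, n = 9 each, exact two-sided permutation p = 0.32). Each library carried its own animal number in the labels, so each was treated as a separate animal. The count table listed 16636 distinct read sequences under 240 mature microRNAs (miRNAs) from 210 hairpin precursors, of which 221 mature miRNAs had enough counts to be tested. Counts over distinct sequences ranged from 9601510 to 34588252 per library, with means, in units of 1000000, of 20.3 ± 5.8 in the high class and 22.9 ± 8.97 in the low class (SD, n = 9 each, exact two-sided permutation p = 0.464). As a check for 1 library listed under 2 names, each pair was compared with counting error alone, which separate animals exceed in any case: the lowest chi-square per degree of freedom among 153 pairs was 62.9.

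The fat miRNA pool was dominated by a few species. miR-10b, encoded within a HOX gene cluster, made up 33.0% ± 3.4 of counts (SD over the 18 libraries), and miR-143-3p, known to promote fat cell differentiation, a further 19.2% ± 1.98. miR-148a-3p held 5.75% ± 1.27, miR-27b-3p, which restrains fat cell differentiation, 4.75% ± 0.546, miR-10a-5p 3.39% ± 0.479, miR-191 2.88% ± 0.535, miR-30a-5p 2.74% ± 0.414 and the endothelial miR-126-5p 2.50% ± 0.56. let-7a, miR-181a, miR-21, let-7c, let-7f, let-7i and miR-30d followed with shares of 2.04%, 1.74%, 1.42%, 1.19%, 1.15%, 1.06% and 0.918%, so that the 15 most abundant miRNAs together held 83.7% of counts. Of these 15, only let-7c passed the edgeR test between backfat classes. miR-21 held 1.68% ± 0.614 of counts in the high class and 1.16% ± 0.153 in the low class (SD, n = 9 each), a difference that did not pass the test (log2 fold change 0.44 ± 0.22, SE, adjusted p = 0.226). miR-103 and miR-378, both tied to lipid and insulin metabolism, had log2 fold changes of 0.23 ± 0.10 (adjusted p = 0.167) and -0.06 ± 0.12 (adjusted p = 0.778) in the same edgeR fit.

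**Figure D1:**
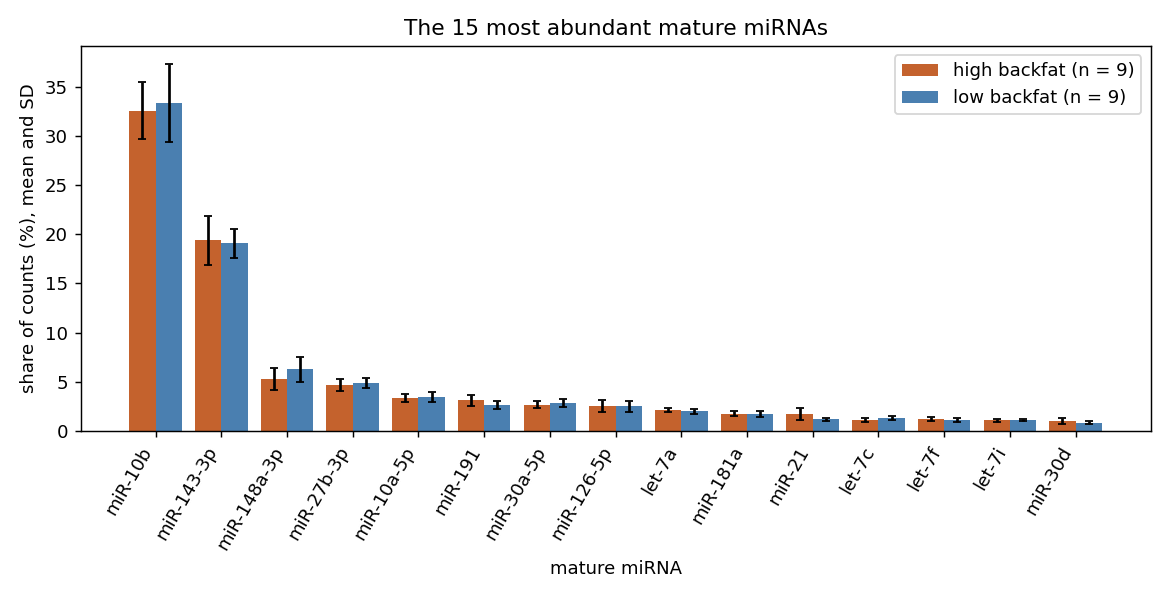
Share of counts (%, vertical axis) of the 15 most abundant mature miRNAs (horizontal axis) in high-backfat and low-backfat pigs; bars are means and error bars SD of 9 libraries each. miR-10b (32.6% and 33.4%) and miR-143-3p (19.4% and 19.1%) stand far above the rest in both classes.

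The comparison of high with low backfat asked which small RNAs differ with fat deposition. When the counts of all sequence forms of a mature miRNA were summed, 8 of 221 miRNAs passed an adjusted p of 0.05 in edgeR's quasi-likelihood test with sex as a covariate, 3 higher and 5 lower in high backfat. miR-365-5p, whose hairpin family is known from brown fat and muscle cell differentiation, showed the largest rise of these 3, with 15.9 ± 6.14 CPM in the high class and 7.54 ± 2.37 CPM in the low class (SD, n = 9 each), a log2 fold change of 1.07 ± 0.23 (SE, adjusted p = 0.0387). The neighbouring miR-222 and miR-221-5p, from a cluster that promotes cell proliferation and restrains fat cell differentiation, rose by log2 fold changes of 0.89 ± 0.22 and 0.99 ± 0.27. miR-222 reached 297 ± 90.2 CPM against 161 ± 57.2, and miR-221-5p 12.3 ± 6.1 against 5.81 ± 1.37. The other arms of the miR-221 and miR-365 hairpins were more abundant than the arms that rose, and did not pass. miR-221-3p was at 417 CPM in the high and 331 in the low class (log2 fold change 0.27 ± 0.18, adjusted p = 0.363). miR-365-3p was at 294 and 263 CPM (0.14 ± 0.15, adjusted p = 0.579).

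Both arms of the miR-199a hairpins, which are abundant in fibroblasts and other mesenchymal cells, fell in high backfat. miR-199a-5p went from 1264 ± 170 CPM in the low class to 954 ± 119 in the high class (log2 fold change -0.38 ± 0.09), and miR-199a-3p from 8040 ± 1290 to 5678 ± 1090 (-0.50 ± 0.13). Of the reads of miR-199a-3p, 79.8% are also listed under another mature miRNA, chiefly miR-199b-3p (-0.41 ± 0.13, adjusted p = 0.0715), so these cannot be separated. miR-136, from the imprinted DLK1-DIO3 locus, fell by 1.20 ± 0.33 on the log2 scale, from 32.7 ± 11.3 to 14.5 ± 9.57 CPM. miR-181c fell by 0.39 ± 0.11 and let-7c, a tumour-suppressor miRNA of the let-7 family, by 0.28 ± 0.07 on the same scale. let-7c alone of the 221 miRNAs had all 9 TMM-scaled values of 1 class outside the range of the other. It was at 10580 ± 365 CPM in the high class against 12940 ± 1423. Chance gives such a separation for 0.00411% of miRNAs, and all 221 were searched. As shares of counts without TMM scaling the classes overlap, at 1.102% ± 0.17 in the high class against 1.275% ± 0.181 (SD, n = 9 each). The adjusted p of these 5 miRNAs, miR-222 and miR-221-5p was 0.0486. Of the 9 high values, 9 lay above the low median for miR-365-5p, 8 for miR-222 and 8 for miR-221-5p, and all 9 lay below it for the 5 miRNAs that fell.

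miR-1306-5p and miR-2320-3p came next, with log2 fold changes of 0.52 ± 0.15 (adjusted p = 0.0517) and 0.54 ± 0.16 (adjusted p = 0.0683). The 8 miRNAs that passed had the same direction in each of the 4 runs of library codes taken alone, with log2 fold changes from 0.69 to 1.59 for miR-365-5p and from -0.36 to -0.12 for let-7c. This is no independent support, as the 8 were chosen by their p in these same libraries. The run AC485 to AC488 also holds only high replicate 9 of the high class. Within the 5 sets of libraries that share sequencing errors and hold both classes, miR-222 had its direction in 3 (lowest -0.23), miR-136 in 4 (highest 0.38), miR-181c in 4 (highest 0.079) and the other 5 in all 5, and DESeq2 called all 8 among 22 miRNAs. The calls were fragile: of the 8, 0 passed with age as a covariate (adjusted p 0.0597 to 0.0696), 0 with limma on the deposited normalised counts, 0 with a term for these sets, 0 without the 4 libraries coded AC485 to AC488, 1 with DESeq2 size factors, 1 without a filter on low counts and 2 without high replicates 6 and 8 (miR-365-5p and miR-221-5p, of 4 miRNAs called then). The log2 fold change of miR-365-5p was 1.10 with age, 1.09 with DESeq2 size factors and 1.07 without the 4 libraries, that of let-7c -0.29, -0.27 and -0.24, and that of miR-222 0.83, 0.90 and 0.64. Leaving out 1 library gave 0 to 13 calls over all miRNAs, with 0 without high replicate 1, 3 or 9 or low replicate 5, 6 or 9, 1 without high replicate 2 or 8 or low replicate 4 or 8, 2 without high replicate 4 or 5, 5 without low replicate 3 or 7 and 13 without high replicate 6.

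**Figure D2:**
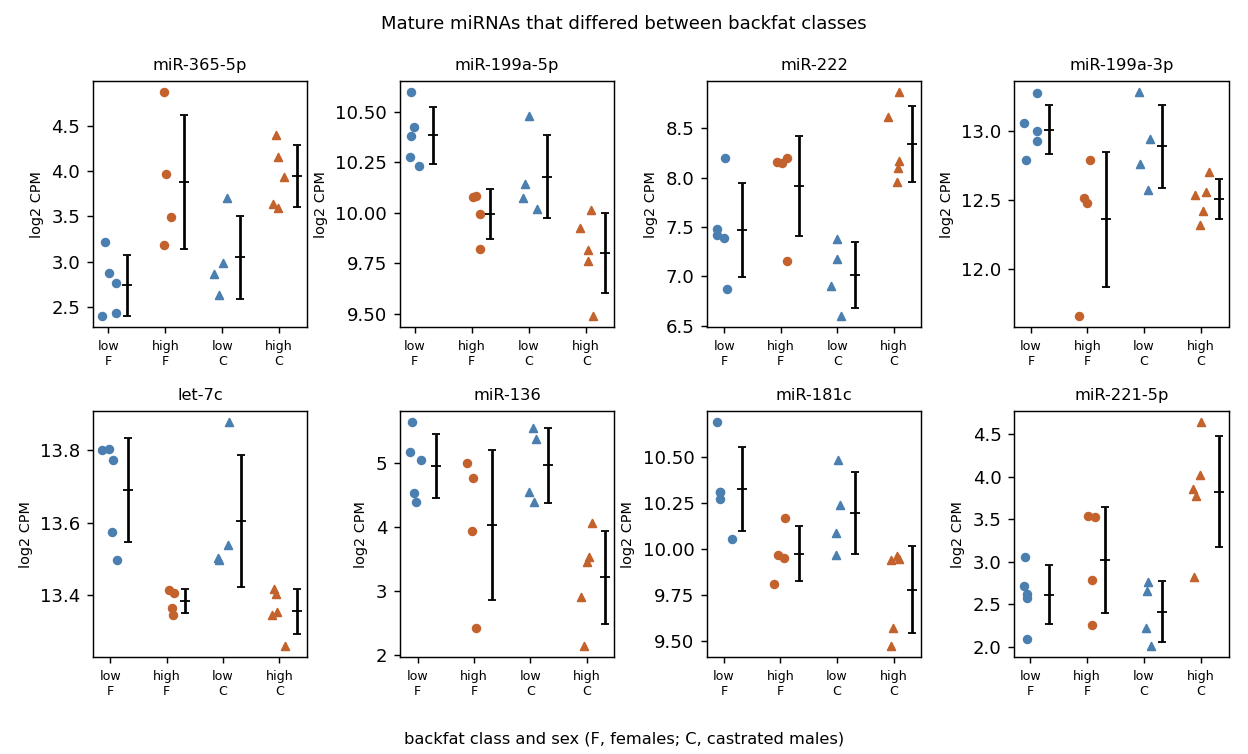
log2 CPM (vertical axis) of the 8 mature miRNAs that differed between backfat classes, by class and sex (horizontal axis); circles are females (F), triangles castrated males (C), and black marks the mean and SD of each cell. The 9 high-backfat points of let-7c all lie below the 9 low-backfat points.

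Among lists of miRNAs fixed by their known roles, the skeletal muscle markers were lower in high backfat. All 4 tested members had negative log2 fold changes: miR-133a-3p -1.10 ± 0.37 (46.3 ± 32.5 CPM against 89.9 ± 44.2, SD, n = 9 each), miR-133b -1.38 ± 0.50, miR-1 -1.56 ± 0.58 and miR-499-5p -0.42 ± 0.19. None passed over all 221 miRNAs, and all 4 passed when adjusted over the list alone; every read of miR-133b (100%) is also listed under miR-133a-3p. Camera placed the list below other miRNAs (adjusted p = 0.0184), and fry gave an adjusted p of 0.0175. The call was lost with camera's estimated correlation (adjusted p = 0.292 with an estimated correlation).

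The fibrosis and extracellular matrix list also lay lower, with 9 of 10 members negative. miR-199a-5p and miR-199a-3p fell, and 3 members, these and miR-199b-3p, fell when adjusted over the list alone. Most reads of miR-199a-3p are also listed under other miRNAs, chiefly miR-199b-3p. These members are therefore not separate, and the list tests count shared reads more than once. Of the collagen-repressing miR-29 family, miR-29a had a log2 fold change of -0.07 ± 0.12, miR-29b -0.24 ± 0.16 and miR-29c -0.22 ± 0.13. miR-214, a neighbour of miR-199a, had -0.28 ± 0.13, miR-199b-5p -0.12 ± 0.15 and miR-181a -0.06 ± 0.12. miR-21, raised in many fibrotic tissues, was the exception at 0.44 ± 0.22, and none of these passed the threshold. Camera gave an adjusted p of 0.0341 and fry 0.0482 (adjusted p = 0.631 with an estimated correlation). The skeletal muscle list lay lower in the same comparison, though not in all the same libraries. In high replicates 2, 4 and 6, all females, miR-133a-3p was at 93.4, 86.7 and 87.6 CPM and miR-199a-3p at 5707, 5849 and 3240 CPM. The log2 fold change of miR-133a-3p was -2.14 ± 0.39 in castrated males and -0.06 ± 0.38 in females. Those of miR-1 (-1.97 ± 0.85 and -1.17 ± 0.83) and miR-499-5p (-0.32 ± 0.27 and -0.51 ± 0.27) were negative in both. With a mean of at least 10 CPM required, only 1 list was called, and the muscle list had no test there. Its members miR-1 (1.5 CPM in the high class, 4.4 in the low) and miR-133b (1.1 and 2.4) fall below that minimum, which leaves fewer than 3. Only 1 list was also called without any 1 of low replicate 1, 6 or 9 or high replicate 9.

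All 5 tested miRNAs of the DLK1-DIO3 cluster had negative log2 fold changes (camera adjusted p = 0.0721), of which miR-136 fell and miR-127 (-0.24 ± 0.16), miR-432-5p (-0.31 ± 0.33) and miR-493-5p (-0.23 ± 0.53) did not pass. The 32 tested arms of miRNAs listed as promoting fat cell differentiation were split into 12 with positive and 20 with negative log2 fold changes (camera adjusted p = 0.486). miR-199a-5p and miR-199a-3p fell among them, and 1 rose and 3 fell when adjusted over the list alone; abundant members such as miR-148a-3p (-0.31 ± 0.17, adjusted p = 0.256) and miR-143-3p (-0.03 ± 0.13) did not pass. The 25 tested arms of miRNAs listed as restraining it were split into 13 and 12 (camera adjusted p = 0.935). miR-222 and miR-221-5p rose and let-7c fell among them, with 2 risen and 2 fallen when adjusted over the list alone. Of 11 inflammation and immune-cell miRNAs 7 were positive (camera adjusted p = 0.129). None passed over all miRNAs and 2 rose when adjusted over the list alone, while miR-146a-5p (-0.03 ± 0.20) and miR-142-5p (-0.04 ± 0.23) stayed near 0. The 9 lipid and cholesterol miRNAs held 3 positive and 6 negative values (camera adjusted p = 0.935), with miR-335 (-0.94 ± 0.30) fallen when adjusted over the list alone. The 9 of the let-7 family held 5 and 4 (camera adjusted p = 0.935), with let-7c fallen. The 17 brown and beige fat miRNAs had 9 positive and 8 negative values, with a median log2 fold change of 0.02, a mean of -0.12 and camera's direction down (adjusted p = 0.935). miR-365-5p rose among them, and miR-193a-3p (-0.69 ± 0.21) and miR-133a-3p fell when adjusted over the list alone.

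Markers of other cell types showed no list-wide shift by camera. The red blood cell list had an adjusted p of 0.935 (miR-451 -0.35 ± 0.26, miR-486 0.47 ± 0.21, miR-144 -0.15 ± 0.26 and miR-363 0.04 ± 0.17), with a median of -0.06, a mean of 0.0026 and camera's direction up. Without low replicate 7 the log2 fold change of miR-451 was -0.020, and without the 4 libraries coded AC485 to AC488 it was 0.23. The white blood cell list had an adjusted p of 0.935 (miR-142-5p, miR-150 0.21 ± 0.23 and miR-142-3p 0.03 ± 0.30), and the neural list one of 0.935 (miR-128 0.28 ± 0.14, miR-9 -0.22 ± 0.20 and miR-138 -0.09 ± 0.64), with a median of -0.09, a mean of -0.01 and camera's direction up. The endothelial miR-126-5p and miR-126-3p (-0.04 ± 0.18 and 0.04 ± 0.14), the epithelial miR-205 (-1.23 ± 0.63) and the liver miRNA miR-122 (-0.76 ± 1.06) belonged to lists with fewer than 3 tested members and had no list test, and none passed alone.

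At the level of single sequence forms, which separates length and mismatch variants of one miRNA, 0 of 7330 tested entries passed in edgeR between high and low backfat. At an unadjusted p under 0.05 there were 643, the lowest adjusted p was 0.0538, and DESeq2 called 158. The entries with the lowest p belonged to miR-103 and miR-199a/b-3p. A mismatch form of miR-103, AGCAGCATTGTACAGGGCTATGTA, had 18.7 ± 2.89 CPM in the high class and 10.4 ± 2.11 in the low class (SD, n = 9 each, log2 fold change 0.84 ± 0.15). It lies at positions 80 to 103 of the extended mir-103-1 precursor and 77 to 100 of mir-103-2. A form that starts 1 base inside the annotated miR-199a-3p, CAGTAGTCTGCACATTGGTTA, also listed under miR-199b-3p, had 67.8 ± 14.8 CPM against 111 ± 16.9 (-0.70 ± 0.13) and lies at positions 79 to 99 of mir-199a-1, 82 to 102 of mir-199a-2 and 78 to 98 of mir-199b. The mismatch forms CAGTAGTCTGCACATTGGTTAA (19.9 ± 4.94 against 33.7 ± 5.5 CPM) and CAGTAGTCTGCACATTGGTAA (1.35 ± 0.259 against 2.45 ± 0.512 CPM) had log2 fold changes of -0.75 ± 0.15 and -0.83 ± 0.15. With a mean of at least 10 CPM required, 59 entries passed, with limma 8 and with DESeq2 size factors 2; leaving out low replicate 2 gave 29, low replicate 4 gave 2, high replicate 6 gave 6 and high replicate 7 gave 26.

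The overall makeup of sequence forms did not differ detectably between the classes. Exact matches to the annotated mature sequence held 51.2% ± 1.09 of counts in the high class and 51.7% ± 1.63 in the low class (SD, n = 9 each), shorter or longer forms 30.3% ± 1.58 and 29.7% ± 1.83, forms with 1 mismatch 17.3% ± 1.97 and 17.4% ± 1.74, and forms with 2 mismatches 1.23% ± 0.0877 and 1.19% ± 0.134. Exact two-sided permutation tests over the 48620 splits gave adjusted p from 0.667 to 0.89 for the 4 shares, with 0 of 4 past the threshold.

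Within castrated males the contrast between 5 high and 4 low pigs was led by the muscle miRNA miR-133a-3p, whose level was 23.7 ± 4.86 CPM in high and 105 ± 44 CPM in low pigs (SD), a log2 fold change of -2.14 ± 0.39 (SE, adjusted p = 0.00423). All 5 high values lay below the lowest low value. miR-133b, which shares its reads with miR-133a-3p, changed by -2.93 ± 0.54. miR-133 represses a regulator of brown fat identity and is abundant in muscle. In the same 4-cell edgeR fit 9 of 221 miRNAs passed, 5 higher and 4 lower in high backfat; this contrast of summed miRNAs was added after the data had been seen.

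Beside the miR-133 family, miR-136 and miR-193a-3p fell by 1.71 ± 0.45 and 1.08 ± 0.28 on the log2 scale in high-backfat castrated males. miR-222 (1.34 ± 0.28, 334 ± 92.4 against 132 ± 30 CPM), miR-221-5p (15.2 ± 6.43 against 5.36 ± 1.32 CPM), miR-146b (1.90 ± 0.44, 462 ± 232 against 124 ± 31.3 CPM), miR-7137-3p (2.10 ± 0.55) and miR-2320-3p (0.79 ± 0.22) rose, with adjusted p from 0.0107 to 0.0462. With the run of library codes as a term, miR-193a-3p (-0.87, adjusted p = 0.119), miR-7137-3p (1.97, adjusted p = 0.0871) and miR-2320-3p (0.66, adjusted p = 0.119) no longer passed, and with age as a term these 3 and miR-136 had adjusted p from 0.0527 to 0.0579. miR-146b acts in a feedback loop that dampens inflammatory signalling. The muscle miRNAs miR-1 and miR-499-5p had log2 fold changes of -1.97 ± 0.85 and -0.32 ± 0.27, neither past the threshold over all miRNAs. miR-133a-3p and miR-133b passed in each of 18 fits that left out 1 library, and 0 miRNAs passed without the 4 libraries coded AC485 to AC488, where miR-133a-3p had -1.67 ± 0.45 (adjusted p = 0.154) and miR-193a-3p -0.44 ± 0.27 (adjusted p = 0.642). The count was 5 with age as a covariate, 5 with the castrated males fitted alone, 2 without low replicate 9, 3 without high replicate 1, 5 without high replicate 5 or 8 or low replicate 8, and 14 without high replicate 6 or low replicate 2.

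**Figure D3:**
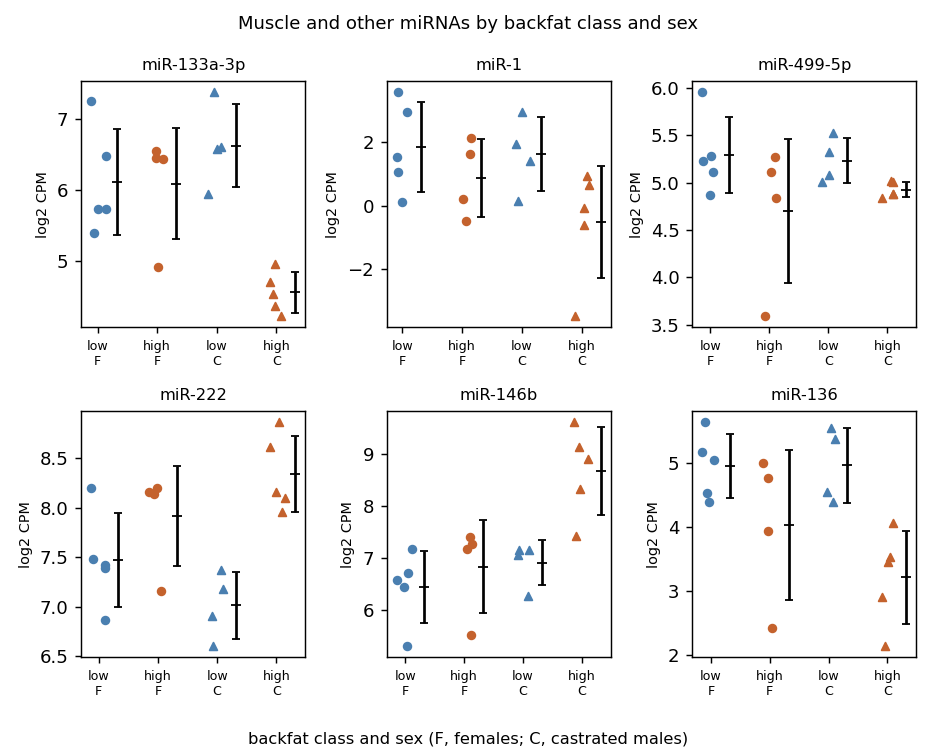
log2 CPM (vertical axis) of miR-133a-3p, miR-1, miR-499-5p, miR-222, miR-146b and miR-136 by backfat class and sex (horizontal axis); circles are females (F), triangles castrated males (C), and black marks the mean and SD of each cell. The 5 high-backfat castrated males lie below the 4 low-backfat ones for miR-133a-3p and miR-136 and above them for miR-222 and miR-146b.

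Single sequence forms passed in castrated males for 12 of 7330 entries, which are 6 distinct sequences, 1 entry higher and 11 lower in high backfat. Among them were 3 length forms of miR-133a-3p. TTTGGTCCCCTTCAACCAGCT, also listed under miR-133b, had 0.284 ± 0.0766 CPM in 5 high and 2.02 ± 0.802 CPM in 4 low pigs (log2 fold change -2.80 ± 0.45), at positions 90 to 110 of the extended mir-133a-1 precursor. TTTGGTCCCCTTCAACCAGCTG had 1.68 ± 0.444 against 7.62 ± 2.09 CPM, and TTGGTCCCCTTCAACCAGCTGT 8.74 ± 1.76 against 41.3 ± 16.4 CPM. The 5′-shortened miR-199a-3p form CAGTAGTCTGCACATTGGTTA fell by 0.92 ± 0.17 on the log2 scale. The remaining entries were forms with 2 mismatches near the detection floor: TCGGATCCGTCTGAGCTTGAA of miR-127, listed at 0 in the 5 high pigs against 0.617 ± 0.415 CPM, and GTCCAGTTTTCCCAGGAATCCCTAT of miR-145-5p, at 0.528 ± 0.31 CPM against 0 in the 4 low pigs. The adjusted p ran from 0.0285 to 0.0487, 600 entries had an unadjusted p under 0.05, and DESeq2 called 286. The count fell to 0 without a low-count filter, with castrated males fitted alone or with each sequence counted once, and to 3 with DESeq2 size factors; leaving out 1 library gave 0 to 13, with 0 without low replicate 1, 3, 6 or 9 or high replicate 1, 3, 4, 5, 6 or 8, 1 without low replicate 4 or 7 or high replicate 9, and 3 without high replicate 2 or low replicate 8.

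In females, 4 high and 5 low pigs, 0 of 221 summed miRNAs passed in edgeR, with 20 at an unadjusted p under 0.05, and DESeq2 also called 0. miR-133a-3p was at 74.4 ± 29.7 CPM in high and 77.8 ± 45.3 CPM in low females (SD), a log2 fold change of -0.06 ± 0.38. Among the miRNAs with the lowest p were miR-365-5p (1.27 ± 0.32, adjusted p = 0.221) and miR-1306-5p (0.70 ± 0.20, adjusted p = 0.271). Of single sequence forms 0 of 7330 passed, with 408 at an unadjusted p under 0.05 and 130 called by DESeq2.

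Whether the backfat difference itself depended on sex was tested as an interaction. The lowest p belonged to miR-133b (-2.86 ± 0.72, castrated males minus females), miR-133a-3p (-2.08 ± 0.54) and miR-204, known to promote fat cell over bone cell fate (-1.54 ± 0.41), each with an adjusted p of 0.11 over 221 miRNAs in edgeR. None passed, 25 had an unadjusted p under 0.05, and DESeq2 called 3. For sequence forms 0 of 7330 passed in edgeR, 463 had an unadjusted p under 0.05, and DESeq2 called 154. Summed miRNAs passing numbered 3 without high replicate 7 and 1 without high replicate 3 or low replicate 5, and sequence forms passing numbered 1 without high replicate 3 or 9 or low replicate 4 or 7.

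Between castrated males and females, with backfat class as a covariate, 0 of 7330 sequence forms and 0 of 221 summed miRNAs passed in edgeR. At an unadjusted p under 0.05 there were 366 and 17 respectively, and DESeq2 called 0 in both. The lowest p belonged to miR-146b, with a log2 difference of 1.13 higher in castrated males (adjusted p = 0.434), and miR-432-5p and miR-127 of the DLK1-DIO3 cluster had differences of -0.97 and -0.42.

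The fixed lists were also compared between the sexes, a comparison added after the data had been seen. All 5 tested miRNAs of the DLK1-DIO3 cluster had negative log2 differences, castrated males minus females (median -0.47, camera adjusted p = 0.000876), and 2 fell when adjusted over the list alone. Of 11 inflammation and immune-cell miRNAs 8 had positive differences (median 0.30, camera adjusted p = 0.00282), and 0 passed when adjusted over the list alone. Markers of other cell types had differences beside these that camera did not call: red blood cells 4 of 4 positive (median 0.34, adjusted p = 0.133), white blood cells 2 of 3 positive (median 0.54, adjusted p = 0.22) and skeletal muscle 3 of 4 negative (median -0.70, adjusted p = 0.22), and the endothelial miR-126-5p and miR-126-3p, with no list test, were at 0.32 and 0.17. Likewise without a list test, the epithelial miR-205 was at 0.62 and the liver miR-122 at 2.44, which passed over its list of 1 alone. Low replicate 7, a castrated male, held 42.8 CPM of miR-122 against 0 to 1.605 in the other low libraries. The red blood cell list was called without low replicate 2 (adjusted p = 0.0343) or without high replicates 6 and 8 (adjusted p = 0.0199), and the muscle list without the 4 libraries coded AC485 to AC488 (adjusted p = 0.0036). The calls of the DLK1-DIO3 and inflammation lists were lost with camera's estimated correlation (adjusted p = 0.326 for the DLK1-DIO3 cluster and 0.329 for the inflammation list with an estimated correlation), with fry (adjusted p = 0.229 and 0.339) and with a term for the sets of libraries that share sequencing errors (adjusted p = 0.216 and 0.425).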

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

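The tests of library-code runs and of muscle fibres, the counts of other splits of the samples, and the 55 miRNAs over which the sex difference was adjusted were chosen only after the results were seen.

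miR-133a-3p and miR-133b were singled out by a test of whether the backfat difference depends on sex, over miRNAs picked after the results were seen. The backfat difference in castrated males minus that in females was -2.86 ± 0.72 for miR-133b and -2.08 ± 0.54 for miR-133a-3p (SE). By edgeR's interaction contrast the adjusted p was 0.0295 for both over the 53 named miRNAs and those called in castrated males, 55 in all, and 0.11 over all 221, where 0 passed and chance cannot be excluded (25 at an unadjusted p under 0.05, highest other split 53). The 2 results are not separate, since every read of miR-133b is also listed under miR-133a-3p.

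For the fall of miR-133a-3p in high-backfat castrated males, 3 technical explanations were tested. With the run of library codes as a term the log2 fold change was -2.31 ± 0.43 (SE, adjusted p = 0.00779), and with the log2 total count as a term -2.18 ± 0.40, which argues against runs and depth as the whole cause. Muscle fibres carried along with the fat stay open: miR-1 had a log2 fold change of -1.97 ± 0.85, like that of miR-133a-3p but from 1257 counts in all 18 libraries, while miR-499-5p had -0.32 ± 0.27. A difference in the fat of castrated males also stays open. As many miRNAs as the 9 called in castrated males came from 1 of 100 splits of the castrated males, the real one included (highest other 4). By these splits a chance result of the grouping is unlikely, but 1 of 100 is the lowest share they can give. The contrast was also added after the data had been seen, so chance cannot be excluded.

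The remaining results have 1 library far from the other 8 of its class, by the gap to the nearest library as a share of the range. This holds for 20 of 116 groups tested, where chance gives about 1 in 20.

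Low replicate 3 had the highest miR-222 of the low class (294 CPM against 96.8 to 178, ratio 0.5877) and the highest miR-432-5p (11.5 against 3.70 to 6.93, ratio 0.5835). Low replicate 7 stood highest for the liver miRNA miR-122 (42.8 CPM against 0 to 1.61, ratio 0.9625), the red blood cell miR-451 (7981 against 1313 to 3530, ratio 0.6675) and miR-193a-3p (819 against 191 to 422, ratio 0.6325), and lowest for let-7f (6658 against 10010 to 12820, ratio 0.5446). Low replicate 9 stood highest for miR-363 (118 CPM against 46.4 to 71.9, ratio 0.643) and the immune-cell miR-142-5p (2734 against 987 to 1662, ratio 0.6139).

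High replicate 6 stood lowest for let-7f (5574 CPM against 10510 to 14330, ratio 0.5636), let-7i (5143 against 9026 to 12480, ratio 0.5288), miR-126-3p (3006 against 5653 to 8370, ratio 0.4935), miR-199b-3p (3974 against 6698 to 8829, ratio 0.5611) and miR-499-5p (11.95 against 28.51 to 38.36, ratio 0.627), and highest for miR-1306-5p (48.0 against 18.5 to 29.9, ratio 0.6111). High replicate 1 had the highest miR-122 (8.65 CPM against 0 to 2.58, ratio 0.7022) and miR-142-3p (123 against 12.03 to 63.26, ratio 0.54). High replicate 9 had the highest miR-144 (329 CPM against 74.6 to 187, ratio 0.5581) and miR-148a-5p (920 against 460 to 668, ratio 0.5472), high replicate 2 the highest miR-138 (8.59 against 0 to 2.79, ratio 0.6758), and high replicate 3 the lowest let-7c (9809 against 10410 to 10940, ratio 0.5344).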

How the results depend on the processing

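Alternatives chosen only after the results were seen were the exact and length variants alone, the error sets, leaving out both libraries of set 6 (high replicates 6 and 8) or the 4 coded AC485 to AC488, each sequence counted once, the sum over all listings, and every alternative for the summed miRNAs of castrated males and of the interaction and for the lists between the sexes. Among the 8 miRNAs that passed, 0 of 223 alternative values changed direction. This is no independent support, as the 8 were chosen by low p in these same libraries. Of 1475 alternative values of the 53 named miRNAs, 1222 kept direction and side of the threshold, 16 gained a call and 151 lost it. All 151 losses fall among the 223 values of the 8 miRNAs that passed, as only these had a call to lose. Another 86 values changed direction, all in 21 miRNAs that had not passed (median size of log2 fold change 0.0626). Few calls clear the threshold by much, since 7 of the 8 share an adjusted p of 0.0486. In simulated data 13.8% of 2-fold changes of a sequence form were found, against 87% for summed miRNAs, where fewer tests and a larger share changed also differ. No paired analysis was possible because the replicate numbers follow the order of accession and no label pairs the animals. The runs of library codes and the sets that share sequencing errors group libraries, not animals, and were fitted as terms.

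Between high and low backfat, 0 sequence forms passed in edgeR (643 at an unadjusted p under 0.05), against 2 with DESeq2 size factors, 59 with a mean of at least 10 CPM (21 higher, 38 lower), 158 with DESeq2 (111 higher, 47 lower), 8 with limma, 18 with exact and length variants only (98 in DESeq2), and 1 without both libraries of set 6 (72 in DESeq2). The count of all summed miRNAs that passed, 8 in edgeR, was 1 with DESeq2 size factors, 1 without a filter, 22 with DESeq2, 0 with limma, 0 with age, 4 without both libraries of set 6 (2 of them among the 8), 0 with the error sets as a term and 0 without the 4 libraries coded AC485 to AC488. In castrated males the 12 entries of sequence forms became 3 with DESeq2 size factors, 0 without a filter and 286 with DESeq2. They became 0 with that sex alone and 0 with each distinct sequence counted once. The 9 summed miRNAs became 5 with that sex alone, 5 with age and 0 without the 4 libraries coded AC485 to AC488. DESeq2 called 130 sequence forms in females, and 154 sequence forms and 3 summed miRNAs for the interaction, where edgeR called 0 of each (408, 463 and 25 at an unadjusted p under 0.05). The 2 lists between the classes became 0 with an estimated correlation and 1 with a mean of at least 10 CPM. The 2 between the sexes became 0 with an estimated correlation, 0 with fry and 0 with the error sets as a term. With a mean of at least 10 CPM they became 1. That minimum leaves the muscle and DLK1-DIO3 lists under the 3 tested members required, so neither was tested there. Counts within 1.5 times can still hold other miRNAs: 7 of the 8 stayed with a mean of at least 10 CPM (9 in all) and 5 with the sum over all listings (8 in all), and in castrated males 6 of the 9 with the run of library codes (10 in all). Apart from leaving out 1 library, the other alternatives run for these counts left them within 1.5 times. The cause of the shifts was not tested, except that leaving out libraries also leaves fewer animals. The minimum of 10 CPM also leaves the muscle and DLK1-DIO3 lists without a test.

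Leaving out 1 library gave 0 to 29 sequence forms between high and low backfat (29 without low replicate 2, 26 without high replicate 7, 6 without high replicate 6, 2 without low replicate 4), 0 to 13 in castrated males, 0 to 1 for the interaction, and 0 to 0 in females and between the sexes. For summed miRNAs it gave 0 to 13 between high and low backfat (13 without high replicate 6), 2 to 14 in castrated males (14 without high replicate 6 or low replicate 2, 2 without low replicate 9), 0 to 3 for the interaction and 0 to 0 in females and between the sexes, and 1 to 3 lists between the classes and 2 to 3 between the sexes. The libraries behind each lower count are named with the results, and the cause was not tested. Of the 18 such fits, miR-365-5p passed in 12, miR-199a-5p in 7, miR-222 and miR-199a-3p in 5, miR-221-5p in 4, and let-7c, miR-136 and miR-181c in 3. In castrated males miR-133a-3p and miR-133b passed in 18, miR-222 in 17, miR-146b in 15, miR-221-5p in 14, miR-7137-3p in 11, miR-136 and miR-193a-3p in 10 and miR-2320-3p in 5.

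Direction changed for named miRNAs that had not passed, with these log2 fold changes, and the cause was not tested. With a mean of at least 10 CPM: miR-143-5p -0.0044. With limma: miR-122 0.89, miR-378 0.037, miR-181a 0.038, miR-493-5p 0.010, miR-143-3p 0.035, miR-142-5p 0.049, miR-146a-5p 0.099. With the sum over all listings: miR-378 0.024, miR-181a 0.028, miR-143-3p 0.037, miR-126-5p 0.026, miR-142-5p 0.049, miR-146a-5p 0.050. With exact and length variants only: miR-143-3p 0.054, miR-146a-5p 0.012. Without both libraries of set 6: miR-150 -0.092, miR-144 0.0063, miR-143-3p 0.086, miR-126-5p 0.11, miR-142-5p 0.078, miR-146a-5p 0.070, miR-143-5p -0.034. With the error sets as a term: miR-30a-5p 0.052, miR-9 0.020, miR-27b-3p 0.017, miR-150 -0.27, miR-122 0.63, miR-144 0.40, miR-378 0.052, miR-143-3p 0.093, miR-126-5p 0.20, miR-142-5p 0.052, miR-146a-5p 0.13, miR-143-5p -0.061. Without the 4 libraries coded AC485 to AC488: miR-451 0.23, let-7f -0.060, miR-122 1.03, let-7a -0.056, miR-126-3p -0.065, miR-142-5p 0.13, miR-138 0.43, miR-146a-5p 0.12, miR-143-5p -0.080. Leaving out 1 library gave ranges that cross 0 for miR-122 (-1.15 to 1.37), miR-378 (-0.11 to 0.0011), miR-493-5p (-0.48 to 0.027), let-7a (-0.014 to 0.10), miR-126-3p (-0.016 to 0.16), miR-363 (-0.019 to 0.19), miR-143-3p (-0.080 to 0.056), miR-126-5p (-0.084 to 0.10), miR-142-5p (-0.13 to 0.12), miR-138 (-0.76 to 0.29), miR-146a-5p (-0.13 to 0.097), miR-142-3p (-0.12 to 0.21) and miR-143-5p (-0.032 to 0.12). Without a change of direction, leaving out 1 library moved the value by over 1.5 times for miR-193a-3p (-0.80 to -0.45), miR-148a-3p (-0.40 to -0.19), miR-127 (-0.35 to -0.14), miR-148a-5p (-0.28 to -0.13), miR-451 (-0.44 to -0.020), miR-9 (-0.30 to -0.14), miR-27b-3p (-0.15 to -0.030), miR-191 (0.044 to 0.16), miR-10b (-0.19 to -0.071), miR-432-5p (-0.49 to -0.15), miR-150 (0.062 to 0.29), let-7i (-0.17 to -0.0089), miR-10a-5p (-0.17 to -0.039), let-7f (0.023 to 0.25), miR-144 (-0.31 to -0.044) and miR-181a (-0.13 to -0.0072), none of which had passed. A mean of at least 10 CPM leaves no value for miRNAs below it. The difference in the share of exact matches (percentage points, high minus low) turned to 0.601 without the most abundant sequence, and that of forms with 1 mismatch to 0.22 with medians and, leaving out 1 library, ranged from -0.557 to 0.343. The cause was not tested.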

Other observations

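The neighbours and DESeq2 calls below, and all tests here except those of sequencing depth and of muscle RNA for the 8 miRNAs, were chosen only after the results were seen.

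Several of the miRNAs that differed with backfat have neighbours within 10000 bases in the annotation of Sscrofa11.1, and the 5 given here share the sign of the miRNA they lie beside. Beside let-7c, miR-99a had a log2 fold change of -0.24 ± 0.10 (SE, edgeR adjusted p = 0.150), and beside miR-181c, miR-181d-5p had -0.20 ± 0.10 (adjusted p = 0.226). Beside miR-199a, miR-214 had -0.28 ± 0.13 (adjusted p = 0.187), and beside miR-136 in the imprinted DLK1-DIO3 cluster, miR-127 and miR-432-5p had -0.24 ± 0.16 (adjusted p = 0.344) and -0.31 ± 0.33 (adjusted p = 0.597).

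DESeq2 called 22 summed miRNAs between the classes, among them the 8 given here. miR-146b, of the inflammatory feedback loop, rose by 1.18 ± 0.32 on the log2 scale (SE, adjusted p = 0.00905), miR-132, also an inflammation miRNA, by 0.48 ± 0.15, miR-92b-3p by 0.74 ± 0.24 and miR-615, encoded within a HOX gene cluster, by 0.75 ± 0.24. miR-335, known from lipid metabolism, fell by 0.93 ± 0.30, miR-195, which restrains the cell cycle, by 0.54 ± 0.18, miR-130a, which represses the fat cell regulator PPARG, by 0.39 ± 0.13, and miR-545-3p by 1.16 ± 0.40. None of these 8 passed in edgeR between the classes.

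For the 8 miRNAs that passed, chance was weighed with 3 technical explanations. As many as 8 came from 1 of 100 splits of the 18 animals, the real one included (highest other 6), the lowest share that 100 splits can give. By these splits chance is unlikely, but they shuffle animals across the error sets, so it cannot be excluded. With a term for the error sets 7 of the 8 stayed under an unadjusted p of 0.05, but 0 passed adjusted, as the median log2 fold change size went from 0.695 to 0.543 and the median SE from 0.176 to 0.206. With the log2 total count as a term 8 stayed (median 0.713, SE 0.178, 5 adjusted), and with the log2 level of miR-133a-3p as a term 8 stayed (median 0.625, SE 0.212, 0 adjusted). The median did not shrink with the total count, which argues against depth as the whole cause. For error sets and muscle RNA, where the medians shrank and 0 passed adjusted, these counts cannot decide. The 8 were chosen by low p in these same libraries, so an unadjusted p of 0.05 is easily kept. Some error sets, such as high replicates 6 and 8, also hold only 1 class. Error sets, muscle RNA, a part played by depth and a difference between the backfat classes stay open.

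High replicates 6 and 8 share a G at read position 7, at 2582 and 2625 substituted reads per 1000000 unsubstituted ones against 12.1 to 441 in the other 16 libraries. The rate was higher in these 2 libraries in 31 of 31 abundant miRNAs, and for A, C and T alike (5533 to 5843 per 1000000 reads with that base, against 121 to 221), as an error of 1 sequencing cycle would give. High replicates 1 and 3, also 1 error set, came next at 430 and 441, so the 4 highest rates are all in high-backfat libraries, but the other 5 high libraries (16.8 to 64.6) lie within the range of the low class (12.1 to 65.4). This argues against backfat class as the whole cause, as does the median of the 7 high libraries other than 6 and 8, at 24.7. Of the 158 entries that DESeq2 called between the classes (109 distinct read sequences), 52 carry this G. Of the same 158, 55 have over 50% of their reads in these 2 libraries, all 55 of them mismatch forms and higher in high backfat.

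By their substitution rates the 18 libraries fall into 8 sets, 7 pairs and the 4 libraries coded AC485 to AC488, with correlations of at least 0.956 for 13 pairs of libraries within sets and at most 0.873 for 140 between them. The labels give 2 samples per lane but no lane numbers, so whether these sets are lanes was not tested.

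Other splits of the samples, 100 for each contrast with the real one included, were counted by the number at an unadjusted p under 0.05 where 0 passed. For high against low backfat 9 splits gave as many as the real 643 sequence forms (highest other 1341), and for castrated males against females 27 gave as many as 366 (highest other 2271) and 19 as many as 17 summed miRNAs (highest other 50). For the interaction 21 gave as many as 463 forms (highest other 1332) and 9 as many as 25 summed miRNAs (highest other 53), and in females 24 as many as 408 forms (highest other 1172) and 10 as many as 20 summed miRNAs (highest other 36). For the lists 22 gave as many as 2 between the classes (highest other 5) and 23 as many as 2 between the sexes (highest other 4), so for none of these 9 results can chance be excluded. For the 12 entries of sequence forms (6 distinct sequences) called in castrated males 4 splits gave as many, the real one included (highest other 82). A split with several times the real count shows that another grouping of these animals can give more calls. Chance therefore cannot be excluded here either. Between the sexes a split likewise gave 2271 against 366, and the cause of such high counts was not tested.

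Of 3474 read sequences listed more than once, 3468 had identical counts in each listing and 6 did not.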
